A study of Mus musculus with 2 samples.

How the data were processed

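DNase-seq, in which the nuclease DNase I cuts accessible chromatin and the cut ends are sequenced, was applied to the gastrocnemius, the large calf muscle, of female F1 mice aged 2 months. The labels describe crosses of the C57BL/6J and CAST/EiJ strains. The labels describe 2 libraries from separate biosamples and number them as biological replicates 1 and 2, and give both the same donor identifier. They form 1 group, so no comparison between groups was possible.

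Per the labels, positions are on the mouse build mm10, and per the README deposited with each library, peaks were called for each library on its own from its filtered alignments. The aligner, peak caller and their versions are not given in the sources used here. Each library had 2 peak lists, in which the authors gave every peak a signal value that is never negative. This deposited signal was used only to describe, rank and filter peaks within a list, across shared peaks for the correlation named below, and in the closing part to count each library's peaks over common signal minimums and to read the step of its values. Its scale is not stated, which limits those comparisons between libraries. A further deposited file listed short segments with the authors' p-value column, read as the false discovery rate of the cut rate. Another file gave the authors' footprints, where cuts are depleted within accessible DNA, with a p-value column that held 0.01 in every row. Sequencing depth was not stated, so the depth behind each peak is unknown. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only.

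The peak list with the smaller median width was to be the main list. This rule had been written on the assumption that the lists were of different kinds, but both turned out to be lists of narrow peaks. The list with the smaller median width was the longer one in both libraries, and it was taken as the main list, with the other as an alternative. This reading was settled after the widths, lengths and overlaps of the lists had been seen. No row of the peak or footprint files lay past the end of a chromosome of GRCm38.

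A peak of one library was called overlapping when it shared at least 1 bp with a peak of the other. Overlapping peaks of both libraries were merged into shared peaks. The merging, and the midpoint taken as the mean of the strongest peak's midpoints in each library, were chosen after the lists had been seen. For comparison, peaks were shuffled within their chromosomes with a fixed seed. Overlap counts were checked with bedtools 2.31.1 and were identical. Location was assigned by midpoint, in the order promoter, exon, intron and intergenic, with promoters set as 1 kb either side of any transcript start in GENCODE release M21. Genome shares came from random positions outside assembly gaps.

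A gene's promoter was called accessible when each library had a peak within 1 kb of a start. The same measure with the added demand that these peaks overlap each other had been seen first, and stands among the alternatives. Gene windows were the gene body plus 10 kb either side. Each list was set against 10000 random lists of protein-coding genes of equal size. They were matched on decile of promoter CpG observed over expected (500 bp either side of the gene's 5' end) or of window length. The number of annotated starts was not matched, and a gene with more starts can be called accessible more easily. Genes are not replicates, so percentiles are given and no p-value. A list was counted as above or below the random lists where it lay outside their central 95%, a line chosen after the first values were seen. The 27 gene lists, the 28 consensus motifs, the design of each comparison and most alternative settings were fixed before the data were examined. Several tests of explanations in the closing part were chosen later, as stated there.

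The text names, per list, the 3 genes with most shared peaks and the 1 with fewest where they matter. It also names 12 genes fixed in advance, the 10 shared peaks with the best mean rank, and the 10 genes with most shared peaks per 10 kb among windows of at least 30 kb. Not every gene that this rule selects is printed. Myh3, Myh8 and Myh13 were added after their values were seen.

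Motifs were sought on both strands in 150 bp windows centred on shared peaks and in windows 1 kb away on both sides that overlapped no peak. A motif was counted as enriched at 1.5 times its background with intervals apart, a line chosen after peak data were seen. Footprint shares of motif sites in shared peaks were divided by those of the same positions moved by 50 bp within the same peaks. The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.

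The functions were tested on simulated data. Of 19955 simulated peaks, 59.5% were planted as overlapping and 59.5% were recovered. For the list percentiles over 21911 genes, 4% of lists drawn at random and 99% of lists with planted accessibility passed the lines. A planted motif in 9.74% of 5000 windows was found in 9.78%.

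Alternatives were a stricter threshold (the strongest 50% of each list), equal numbers of the strongest peaks, other overlap, promoter, window and background settings, and each library on its own. Leaving out peaks under a signal of 0.3 and a reversed consensus as footprint control were added after seeing the data. The mice carry 2 parental genomes and positions are on the reference, so sites that differ in CAST/EiJ may be mapped less well. This was not measured.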

Results

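Chromatin accessibility was measured by DNase-seq in the gastrocnemius, a mixed but mainly fast calf muscle, of female F1 mice aged 2 months. The group held 2 libraries. The labels give them separate biosamples, described with different numbers for the female, but 1 donor identifier, so whether they came from separate animals is not settled and each SD may be partly technical. Replicate 1 had 66984 peaks covering 14.5 Mb, and replicate 2 had 258342 peaks covering 42.5 Mb, 3.86 times as many. The mean was 162663 ± 135311 peaks (SD, n = 2), so no typical number can be given from these libraries. Median peak width was 208 bp in replicate 1 and 160 bp in replicate 2. Sequencing depth is unknown. The segments with a false discovery rate of 0.05 or below covered 22.1 Mb in replicate 1 and 71.3 Mb in replicate 2, of which 64.1% and 58.8% lay in that library's own peaks.

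Sites of the shorter list mostly recurred in the longer one. Of replicate 1's peaks, 51474 (76.8%, 95% exact interval 76.5 to 77.2) overlapped a peak of replicate 2, against 3.87% for shuffled positions. Of replicate 2's peaks, 52182 (20.2%, 20.04 to 20.35) overlapped a peak of replicate 1, against 1.00% when shuffled. Recurrence followed peak strength. When each list was split into 5 parts of equal size by signal, 99.5% of replicate 1's strongest part overlapped and 23.9% of its weakest. In replicate 2 these shares were 76.0% and 0.850%. With the same number of strongest peaks in each, 64.8% and 65.3% overlapped. The overlapping peaks merged into 49160 shared peaks. Across them the authors' log2 signals had Spearman's rho of 0.899 and Pearson's r of 0.928. These are correlations across peaks, which are not independent replicates.

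The 10 shared peaks with the best mean rank were all promoter peaks. The best mean rank belonged to a peak on chromosome 15 (76351101 to 76351340, mm10) 78 bp from a start of Maf1, a repressor of RNA polymerase III. The peak at Hspa5, which encodes the chaperone BiP of the endoplasmic reticulum, lay 1 bp from a start, on chromosome 2 (34771821 to 34772100). The others were nearest to Hsp90b1, P4hb, Stip1, Bahcc1, Arrdc4, Prkaca, Rfx1 and AA474408.

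Shared peaks were concentrated at promoters. Of them, 44.4% had their midpoint within 1 kb of an annotated start, against 6.03% of the genome, a 7.36-fold excess. The excess was 11.5-fold with promoters of 500 bp, 4.62-fold with 2 kb and 11.05-fold with starts of protein-coding genes only. Without replicate 1 it was 3.34-fold, but there all 258342 peaks of replicate 2 count and not shared peaks only. Exons held 4.88%, introns 28.2% and intergenic DNA 22.5%, against 3.19%, 38.4% and 52.4% of the genome. Within each library's own list the promoter share was 40.6% in replicate 1 and 20.1% in replicate 2, with a mean of 30.4 ± 14.5% (SD, n = 2). Of 21911 protein-coding genes, 13187 (60.2%) had a promoter peak in both libraries.

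Genes of the contractile apparatus and of fuel use had accessible promoters. All 30 genes of the sarcomere and of excitation-contraction coupling had a promoter peak in both libraries, against a median of 43.3% in random lists matched on CpG content (percentile 100). So did all 16 glycolysis genes (percentile 100), all 20 genes of fatty acid oxidation and mitochondria (percentile 100), and all 18 circadian clock genes (percentile 99.5). Fast fibre genes reached 19 of 22 (percentile 100), and the genes without a shared promoter call were Myh2, Myh1 and Myh4. Lists can share genes, with 394 entries for 377 distinct genes. Pfkm, Pygm and Eno3 stood in both the fast fibre and the glycolysis list, so these 2 results are not independent. Myogenic regulators reached 19 of 20 (percentile 98.8) and neuromuscular junction genes 12 of 14 (percentile 99.9). Slow fibre genes reached 11 of 18 (percentile 99.1), but lay at percentile 53.6 without matching and at 92.6 with the strongest peaks only. Without replicate 1 they reached 17 of 18 (percentile 100), against 19 of 22 fast fibre genes. In all, 11 of 27 lists lay above the central 95% of random lists and 4 below it. Without replicate 1 the housekeeping and circadian lists fell inside it (both at percentile 95.8), though all 16 and all 18 genes still had a promoter peak. Their share was at its ceiling, so these percentiles fell only because more random lists were fully accessible too.

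**Figure D1:**
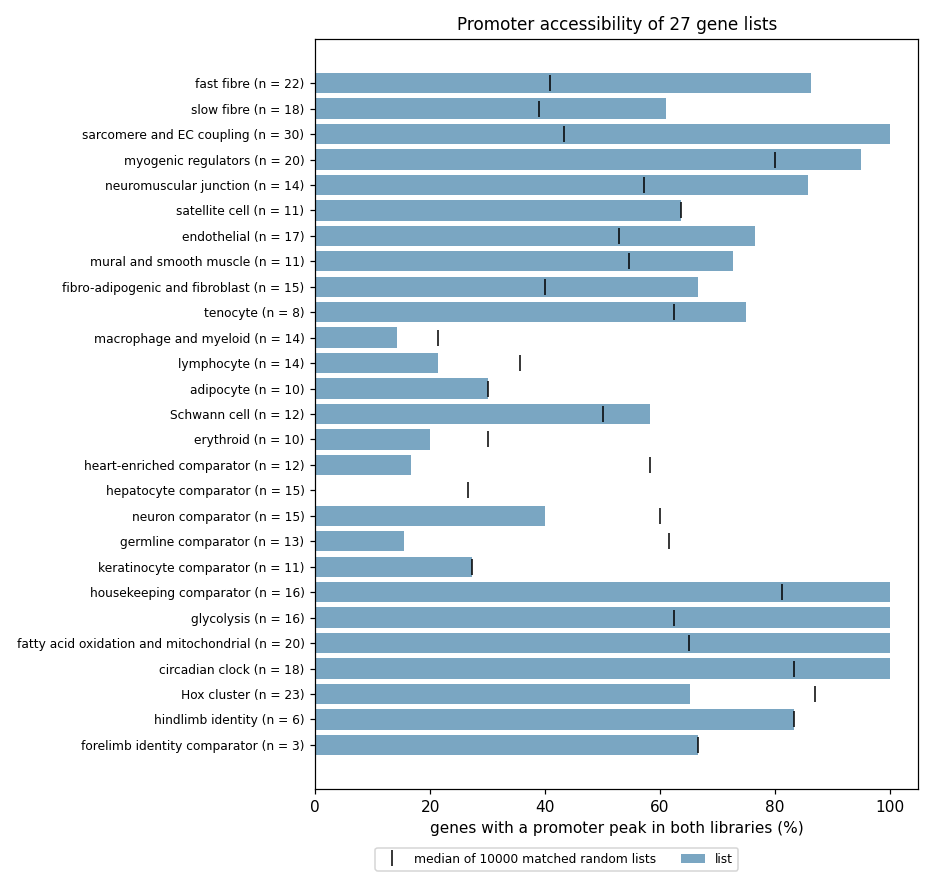
Share of genes in each of 27 lists with a promoter peak in both libraries (bars, in percent), beside the median of 10000 random lists matched on promoter CpG content (black ticks). Sarcomere and glycolysis genes stood at 100%, and hepatocyte genes at 0%.

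Markers of other cells of the tissue were unevenly represented. Endothelial genes had promoter peaks in both libraries at 13 of 17 (percentile 99.3) and fibroblast genes at 10 of 15 (percentile 98.0). Mural and smooth muscle genes reached 8 of 11 (percentile 93.3), tenocyte genes 6 of 8 (percentile 83.2), Schwann cell genes 7 of 12 (percentile 81.2) and satellite cell genes 7 of 11 (percentile 56.0). Adipocyte genes reached 3 of 10, lymphocyte genes 3 of 14, erythroid genes 2 of 10 and macrophage genes 2 of 14, none past either line. Without matching, the lymphocyte, erythroid and macrophage lists lay below it (percentiles 0.265, 0.695 and 0.01). In replicate 2 alone, 10 of 14 macrophage promoters had a peak (percentile 99.1), and all 11 mural promoters did (percentile 99.5). Neither the endothelial nor the fibroblast list stayed above the central 95% with promoters of 500 bp (percentiles 93.9 and 95.4), with the strongest peaks only (68.7 and 94.7) or without matching (91.3 and 68.2). With equal numbers of peaks the fibroblast list lay at 95.7.

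Hepatocyte, heart-enriched and germline genes had fewer accessible promoters than matched random lists. No hepatocyte gene of 15 had a promoter peak in both libraries (percentile 0.445). Among heart-enriched genes 2 of 12 did (percentile 0.03) and among germline genes 2 of 13 (percentile 0.005). Neuron genes stood at 6 of 15 (percentile 3.15), inside the central 95%. They lay below it with promoters of 500 bp (percentile 0.185), the strongest peaks (0.04), equal numbers (0.265) and promoter peaks that overlap each other (0.820), the measure seen first, but at 44.1 without replicate 1. Keratinocyte genes stood at 3 of 11 (percentile 39.8, but 1.73 without matching), while housekeeping genes stood at 16 of 16 (percentile 99.4). Albumin, Alb, the main plasma protein of liver, had no peak in its window in either library. The Hox genes, which set position along the body, reached 15 of 23, below lists of equal CpG content (percentile 0.930). Without matching they were at percentile 67.6, with the strongest peaks at 4.60 and without replicate 2 at 18.1. Hindlimb genes reached 5 of 6 and forelimb genes 2 of 3, near their random medians. The hindlimb gene without the call was Pitx1, which had a promoter peak in replicate 2 only. The forelimb gene without it was Tbx5, with a promoter peak in neither library.

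Shared peaks were counted around the genes of each list as well. The median fast fibre gene had 9 shared peaks in its body and flanks of 10 kb, against 2 in random lists of equal window length (percentile 100). Sarcomere genes and myogenic regulators each had 7.5, glycolysis genes 8, circadian genes 7 and neuromuscular junction genes 5, all above percentile 99. Counted in single libraries, where every peak counts and not shared peaks only, these medians were higher or, for circadian genes in replicate 1, equal. In replicate 2 they were 20 for fast fibre genes (random lists 4.5), 27.5 for sarcomere genes, 22.5 for myogenic regulators, 20 for glycolysis, 15 for circadian and 14 for neuromuscular junction genes. In replicate 1 they were 15.5 (random lists 2), 10.5, 9.5, 11, 7 and 5.5, with all of these lists above percentile 99 in both libraries. Genes of fatty acid oxidation had 4 (percentile 99.8, and 10 in replicate 2). Hox genes had 4 (percentile 100, with 12 in replicate 2 and 8 in replicate 1). Windows of neighbouring Hox genes overlap, so the same peaks count for several of them. Random lists were drawn gene by gene across the genome, so the Hox percentile overstates how unusual the list is. Housekeeping genes had 3 (percentile 98.1). The housekeeping list was inside the central 95% with either library left out (96.3 without replicate 1, 94.7 without replicate 2), without matching (93.7) and with 50 kb flanks (95.9), where fatty acid oxidation was too (96.5). Slow fibre genes had 3 (percentile 92.6), and satellite cell genes 4 (percentile 96.4). The medians of the endothelial, mural, fibroblast and tenocyte lists were each 2. Without replicate 1 the endothelial median of 20 (percentile 99.9), the mural median of 19 (percentile 99.5) and the slow fibre median of 12 (percentile 99.2) lay above the central 95%. Hindlimb genes had 3.5 (percentile 97.0). The 3 with most were the Hox genes Hoxa11, Hoxd10 and Hoxc10, with 19, 5 and 4, while Pitx1 had none. The hindlimb list lay above the central 95% without replicate 1 (18.5, percentile 99.4), with the strongest peaks (98.8) and with equal numbers (98.2). It lay inside without replicate 2 (93.4), without matching (91.2) and with 50 kb flanks (95.9). In all, 9 lists, the Hox list among them, lay above the central 95%. The heart-enriched list lay below it (percentile 2.38, but 30.3 without replicate 1 and 6.62 without replicate 2). Its median was 0, the lowest possible, so its percentile turned on how many random lists also had 0.

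Atp2a1, the fast-fibre calcium pump of the sarcoplasmic reticulum, had 32 shared peaks in its window. The gene lies on chromosome 7 from 126445858 to 126463108, and its window held 8.59 per 10 kb, the most among windows of at least 30 kb with all deposited peaks. With the strongest peaks only it had 15, fewer than the 20 of the shorter window of Dapk3. Ttn, the giant elastic sarcomere protein, had 44 over a far longer window, but 6 with the strongest peaks only. Acta1, skeletal actin, had 17 and Ckm, muscle creatine kinase, had 16. Pfkm, the muscle phosphofructokinase, had 21 and Pygm, the muscle glycogen phosphorylase, had 19. Among regulators Nfix had 38, Rora 36 and Mef2d 25, and Myod1 had 6, Myog 7 and the satellite cell gene Pax7 5. These windows differ in length, from 22.6 kb for Myod1 and Myog to 754 kb for Rora. Per 10 kb of window Nfix had 3.15, Rora 0.477, Mef2d 5.03, Myod1 2.65, Myog 3.10 and Pax7 0.429. Per1, a core clock gene, had 27, the most of the circadian list. Bcl9l had 41 and Mafk 26. With the strongest peaks only, Mafk had 5, Pfkm 10, Rora 20 and Bcl9l 28, while Nfix kept 35, Ckm 13 and Acta1 12. In the Hoxa cluster, Hoxa9 had 37 (16 with the strongest peaks only), Hoxa10 32 (15) and Hoxa13 none. Windows in this cluster overlap, so their counts are not independent.

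Fast fibre genes carried more shared peaks than slow fibre genes. The medians were 3.08 and 0.403 per 10 kb of window, a difference of 2.68 that exceeded those of random pairs of lists (percentile 100). Without replicate 1 the medians were 5.11 and 2.74, and the difference was 2.37 (percentile 99.97). This setting also counts every peak of replicate 2 and not shared peaks only, so it does not show what the low slow value rested on. With equal numbers of strongest peaks the medians of shared peaks were 2.21 and 0.403. Without replicate 2 the difference was 3.46, and with 50 kb flanks it was 0.778 (percentile 100). Among slow genes Nfatc1, a calcineurin-regulated factor, had 31 shared peaks, Myl6b and Tpm3 had 5 each, and Myh7, the slow myosin heavy chain, had none. The window of Nfatc1 was the longest of these, and per 10 kb Nfatc1 had 2.44, Myl6b 2.04 and Tpm3 1.04. With the strongest peaks only they had 12, 5 and 2 shared peaks. Replicate 2 alone had 34 peaks in the Myh7 window, 13 of them near its annotated starts. The strongest of these 13 had a signal of 0.375, and 48.4% of replicate 2's peaks were stronger.

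The fast myosin genes were an exception among fast genes. Myh2, Myh1 and Myh4, which encode the heavy chains of fast fibres, had no shared peak in their windows. From the start of Myh2 to the end of Myh13 (chromosome 11, 67171027 to 67371586) there was no shared peak. Between Myh3 and Myh2 lay 21 shared peaks, from 67104821 to 67153450, at 3.06 per 10 kb. Replicate 1 alone had 2 peaks at the Myh4 promoter. In the windows of Myh2, Myh1 and Myh4, replicate 2 had 3, 2 and 8 peaks, and replicate 1 had 0, 0 and 3. The span from Myh2 to Myh13 held 243 segments with a false discovery rate of 0.05 or below in replicate 1 and 568 in replicate 2, at percentiles 36.1 and 37.0 of 608 spans of its length on the chromosome. The median span held 895 and 1419 segments, and spans in assembly gaps were not left out.

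**Figure D2:**
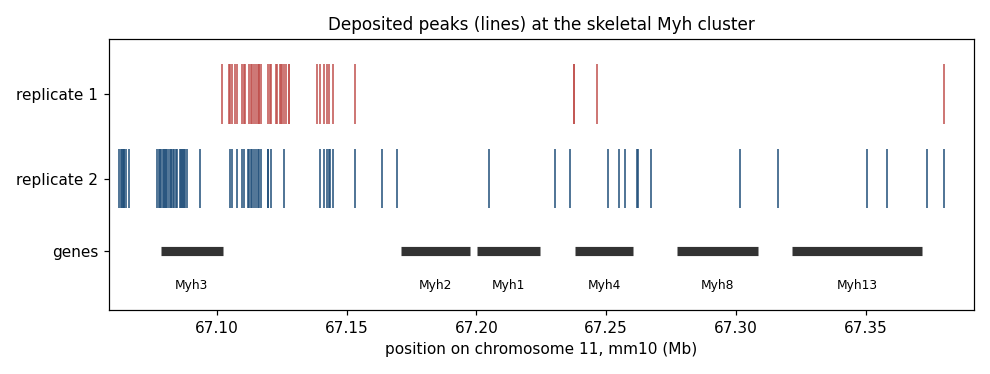
Deposited peaks of each library (vertical lines) along chromosome 11 in mm10, with gene bodies in black and position in Mb on the x axis. Of the shared peaks drawn, 21 lie between Myh3 and Myh2, none from Myh2 to Myh13, and 1 past the end of Myh13.

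Consensus sites of 28 kinds were sought in shared peaks. The CAGCTG E-box bound by MYOD and MYOG was in 19.2% of windows, against 6.63% of flanking windows, a 2.89-fold excess. Against shuffled sequences of equal dinucleotide counts, 12.7% of which held it, the excess was 1.51-fold. In distal shared peaks it was in 24.7% (3.54-fold), and at promoters in 12.4% (2.01-fold). CTCF sites, bound by the insulator factor, showed a 29.7-fold excess (13.2-fold against shuffled sequences, 18.5-fold without replicate 1), and AP-1 sites a 2.20-fold one (3.07-fold distal, 1.02-fold at promoters). At promoters NRF1 sites were 50.6-fold, ETS sites 22.4-fold and SP/KLF sites 13.2-fold more frequent. Over all shared peaks these were 21.9, 12.5 and 9.03-fold, against 30.4, 7.02 and 5.53-fold with shuffled sequences and 8.22, 5.10 and 4.06-fold without replicate 1. The motif values without replicate 1, that of CTCF included, are for all peaks of replicate 2 and not shared peaks only. MEF3 sites were 2.02-fold more frequent, TEAD sites 1.27-fold, under the line, and SRF CArG boxes stood at 0.839 with intervals that overlapped. Against shuffled sequences TEAD and SRF sites passed the line (1.93 and 1.69). Altogether 17 of 28 motifs passed 1.5-fold with intervals apart. MEF2 sites were less frequent than in flanks (0.568-fold) but 17.9-fold more frequent than in shuffled sequences. RUNX, FOX and POU sites turned direction in the same way, and the flanks were not matched on base composition.

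The authors' footprints numbered 153010 in replicate 1 and 338761 in replicate 2, with a mean of 245886 ± 131346 (SD, n = 2). Of these, 88.7% and 91.1% lay in the library's own peaks. Within shared peaks 50.8% of replicate 1's and 45.9% of replicate 2's footprints overlapped one of the other library, against 26.6% and 24.4% after a move of 50 bp. CTCF sites lay in footprints in 67.3% of 1359 cases in replicate 1 and 72.1% in replicate 2, a mean of 4.46 ± 0.812 times the moved positions (SD, n = 2). NRF1 sites stood at 2.71 ± 0.0184 (4.51 in both libraries with a move of 30 bp) and SP/KLF sites at 2.08 ± 0.0028. The E-box CAGCTG stood at 1.22 ± 0.00826, with intervals apart in both libraries but under the 1.5 line. MEF2 sites were above their moved positions in replicate 1 (1.33) and below in replicate 2 (0.793). The call in replicate 2 was lost with a move of 30 bp (0.958) and with the strongest peaks (0.887), and against the reversed consensus it turned to above (1.80). In both libraries 11 motifs passed 1.5-fold.

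**Figure D3:**
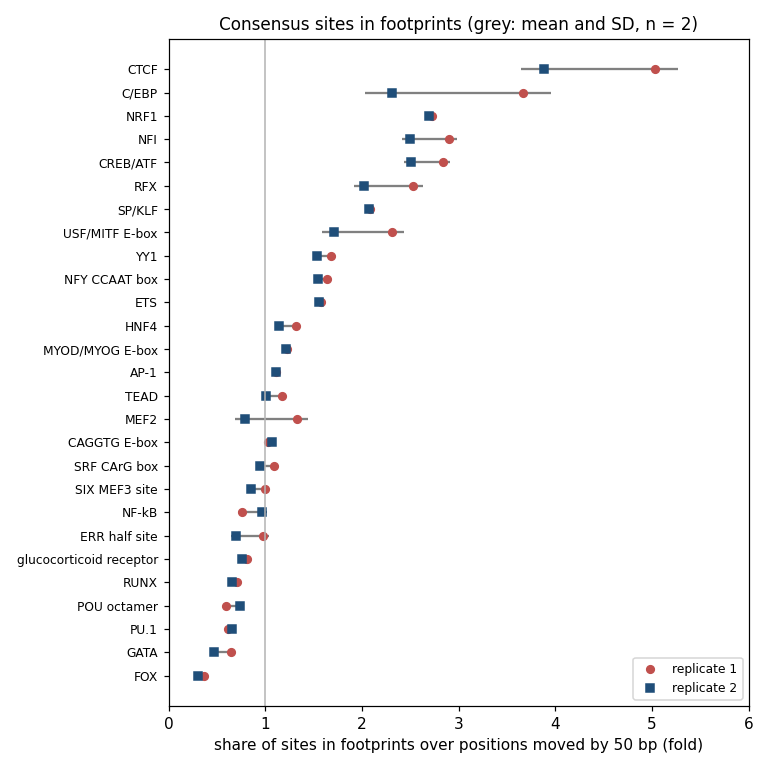
Share of consensus sites that overlap a footprint, divided by the share for the same positions moved by 50 bp (x axis, fold), for 27 motifs. Points are the 2 libraries and grey bars the mean with SD (n = 2); CTCF stands highest at 4.46 and FOX lowest at 0.335.

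The X chromosome had fewer peaks per Mb than the autosomes. Its density was 0.398 of the autosomal median in replicate 1 and 0.470 in replicate 2, or 0.434 ± 0.0508 (SD, n = 2). With the strongest peaks only it was 0.233 and 0.284, and with peaks under a signal of 0.3 left out 0.331 and 0.350. With equal numbers of peaks it was 0.398 and 0.230, which turned the order of the libraries. There replicate 1 entered with its whole list but replicate 2 with its strongest peaks only. Both libraries listed peaks on Y, 50 and 108, and no promoter of the 9 male-specific genes examined had a peak in either.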

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

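Of 91 values of main results recomputed under alternatives, 61 stayed the same and 30 moved. Counts within 1.5 times were called the same. So were overlap shares inside the main interval and promoter shares of peaks within the SD between libraries (14.5 points). A count called the same can hold other members. With shuffled sequences 21 motifs passed the line against 17, and 15 were in common. Leaving out peaks under a signal of 0.3, the demand that promoter peaks overlap each other, and the reversed consensus were chosen after the data were seen. No paired analysis was possible because the samples form 1 group. With 2 libraries, leaving out 1 always moves a mean by the same fraction of the SD, so that check says nothing on the stability of means. The mean number of peaks was 81331.5 with the strongest peaks only, 90037 with the other peak file and 104976 without weak peaks, and ran from 66984 to 258342 by library. The overlap share of replicate 1 was 57.6% with reciprocal overlap of 50%, 96.6% with the strongest peaks of each list, 64.8% with equal numbers, 77.7% with the other file and 86.6% without weak peaks. That of replicate 2 was 14.9%, 25.6%, 65.3%, 22.1% and 32.9%, and 20.4% on autosomes. Spearman's rho was 0.906 with reciprocal overlap and 0.874 with equal numbers. The promoter share of peaks ran from 20.1% to 40.6% by library. The number of lists below the random lists at promoters was 7 without matching. Around genes it was 0 with 50 kb flanks, 2 without matching, 0 with equal numbers and 0 without weak peaks, and 0 to 1 by library. The heart-enriched median was 0 in the main setting, with equal numbers and without weak peaks (percentiles 2.38, 3.725 and 2.735). In these settings the call turned on ties with random lists at 0. The X ratio was 0.258 with the strongest peaks, 0.314 with equal numbers and 0.340 without weak peaks. The share of listed segments in peaks was 36.7% for the strongest peaks, as follows from fewer peaks. Footprints ran from 153010 to 338761 by library. With shuffled sequences as background, sites of MEF2 (17.9), RUNX (1.74), FOX (3.03) and POU (1.90) turned from below to above their background, and the CAGGTG E-box from above to below (0.833). Without matching, the Hox promoter share of 65.2% lay at percentile 67.6 instead of 0.930. MEF2 sites in footprints of replicate 2 turned from below to above with the reversed consensus (1.80). Apart from these 7, single lists and motifs, in peaks and in footprints of each library, were the same in 677 comparisons, lost their call in 35 and gained one in 31. Except where stated, the cause was not tested. Unknown depth limits how the library sizes can be read.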

Other observations

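Of the tests below, those on the peak threshold, on depth and on peak number were chosen after the values were seen; those on motifs of single-library peaks, repeated sequence and segments at the Myh promoters were written before. The test of MEF2 sites against shuffled sequences was added after the first motif test, with its prediction written before its own value was seen, and the CTCF control was chosen after all motif values were seen. The peaks on Y that both libraries shared had a median signal of 0.503 in replicate 1 and 0.485 in replicate 2, and the other Y peaks 0.0995 and 0.0785.

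Replicate 2 had 3.86 times as many peaks as replicate 1. A looser effective threshold in replicate 2 cannot be told apart from other explanations: the ratio was 3.57 in the shorter lists, into which a looser threshold could carry over. At a common signal minimum it was 2.67 at 0.3 and 1.95 at 1, but 3.33 at 5 and 7.66 at 10, and the scale of the signal is not stated. Deeper sequencing stays open for the same reason, since replicate 2 would hold 1.04 times the tags of replicate 1 only if 1 step of the signal were 1 tag of a library scaled to a fixed total. Differences in enrichment between libraries were not tested, and the design names no biological difference between them.

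With equal numbers of strongest peaks, promoters of the 120 markers of other cell types were still more often open in replicate 2. They stood at 75 against 60, a difference of 12.5 percentage points at percentile 100 of random lists. So the number of peaks is not the whole cause. Of 79 fibre genes, 73 were open in replicate 2 against 75 in replicate 1 (percentile 13.1). Nearly all were open in replicate 1 already, so they had little room to gain and are a weak contrast. Of 66 comparator genes 15 were open against 14 (percentile 55.6). With all deposited peaks the comparators stood at 30 against 14 (percentile 98.1). A candidate explanation was more nuclei of other cell types in replicate 2, which predicted more PU.1 and ETS sites and fewer MEF2 sites in its own peaks. The prediction was not met, since 1 of the 3 motifs went that way beyond its interval (PU.1, 2.20-fold against 1.33-fold), ETS intervals overlapped, and MEF2 was higher in replicate 2 both over flanks (0.529 against 0.288) and over shuffled sequences (10.3 against 4.11, a ratio of 2.49). These tests decide nothing, because CTCF, which serves all cell types, was also higher in the peaks of replicate 2 alone (47.1 against 15.3 over flanks, intervals apart), as were 20 of 27 motifs, and replicate 1 entered with its whole list but replicate 2 with its strongest peaks only, so more nuclei of other cell types cannot be told apart from a difference in peak strength. The lists within the 120 markers, which are part of the pattern and no separate evidence, moved unevenly, from 6 against 2 for macrophage promoters (percentile 99.9) to 6 and 6 for tenocyte and 2 and 2 for erythroid promoters.

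Myh2, Myh1 and Myh4 had no shared promoter peak. Sequence repeated elsewhere in the genome is argued against for these promoters. A median of 0.710% of the 31-mers in the 3 promoters recurred, against 2.08% in 300 random genes (percentile 33.9). The median of the 19 other fast fibre genes was lower, at 0.152%, though Myoz1 among them stood at 11.7%. Repeats in the rest of the gene windows and of the span were not tested. Accessibility under the peak threshold cannot be told apart: 0 of the 3 promoters held listed segments in both libraries, but the segment list ends at a rate of 0.05, which 99.6% and 99.9% of peaks reach, so weaker sites would not be listed. Myh4 held 319 bp of segments in replicate 1 and Myh1 held 16 bp in replicate 2. The span from Myh2 to Myh13 held 243 and 568 segments, under the medians of 895 and 1419 for spans of its length. It was not extreme among these spans (percentiles 36.1 and 37.0), but spans in assembly gaps were not left out. A strain variant against the reference was not tested, and no biological explanation was tested.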
